A study of Homo sapiens with 36 samples.

How the data were processed

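Ribosome profiling sequences the short stretches of messenger RNA that ribosomes cover, and RNA sequencing of the same kind of cells gives the amount of the messages. The series holds 36 libraries from 2 human cell models of transformation. MCF10A-ER-Src is a breast epithelial line with a Src kinase fused to the ligand-binding part of the oestrogen receptor, so that 4-hydroxytamoxifen switches the kinase on. The cells were induced at 1 µM for 1, 4 or 24 h. Ethanol, the vehicle, and cells at 0 h served as uninduced controls. BJ is a line of skin fibroblasts, and its derivatives are labelled EH, EL and ELR. The labels do not spell these names out. As background, such BJ series carry telomerase (hTERT), then the early region of SV40, then an oncogenic HRAS. Footprint libraries were made after 100 µg/ml cycloheximide for 90 s, which arrests elongating ribosomes, or after 2 µg/ml harringtonine for 5 min, which holds ribosomes at start codons while the others run off. RNA was depleted of ribosomal RNA by hybridisation and made into libraries by a tagging method.

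The deposited values are counts, per the labels aligned by the authors with TopHat to hg19, whose assembly is GRCh37. The submitters' processing notes give no versions, and the counting program is not given in the sources used here. Each library has its own table of 36499 transcripts with 33993 RefSeq accessions and 19137 gene symbols. All accessions were protein-coding (NM_), so a planned comparison with non-coding transcripts was not analysed here. Values were checked to be whole numbers. Of 7526 symbols with several transcripts on the primary chromosomes, 1575 had equal counts on all of them in every library. Whether such transcripts share a coding region was not checked. The log2 RNA count rose with log2 coding length (slope 0.33, SE 0.018) but not with the length of the untranslated regions (slope −0.07, SE 0.013, over 9490 genes). The counts were therefore taken to cover coding regions, and a read can be counted in several isoforms. On that reading, harringtonine counts are sums over whole coding regions and not heights of start peaks. For 7636 symbols with several transcripts, the transcript with the highest mean count in the libraries compared stood for the gene. Of the symbols, 17590 were placed on GRCh37 with the GENCODE release 44 annotation mapped to that build. Transcripts on alternative or unplaced sequences numbered 1866, in 211 symbols.

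Total counts ranged from 2225844 to 3008760 in the ER-Src RNA libraries, 1334866 to 3628073 under cycloheximide and 163092 to 374359 under harringtonine. In the BJ lines they ranged from 2071883 to 2551358, 1178012 to 2606344 and 129175 to 214806. Expression is given as normalised read count (CPM, a count scaled to a common library size) after trimmed mean (TMM) scaling, and a mean is given with its SD and n. A fold against a group with no counts was computed against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

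Groups followed the labels (27 groups of libraries). Footprints and RNA were fitted with edgeR 4.0.16 quasi-likelihood models in R 4.3.3, after its filter on low expression (minimum count 10, total 15), with two-sided tests and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. There were 18 comparisons tested. The uninduced arm of the ER-Src footprints pooled 4 libraries: 0 h (replicate 1) and ethanol at 1, 4 and 24 h (all replicate 2). Vehicle and replicate number therefore cannot be told apart in that arm, while each tamoxifen time has replicates 1 and 2. Ribosome loading is the change in cycloheximide footprints beyond the change in RNA, tested as an interaction term. A line by drug term tested whether a difference between lines depended on the drug. Arms with a single library were assumed to vary like the replicated groups. Where every arm had 1 library, ratios of CPM with a pseudocount of 1 were described without a test, for genes with at least 10 CPM in one of the libraries. Lists in such pairs were set against 10000 random lists drawn from 20 bins of expression.

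Gene lists numbered 24 and 22 were tested as sets where at least 5 members were measured, with camera of limma 3.58.1 at its preset correlation of 0.01. These calls were repeated with the correlation estimated from the data and with fry. The lists reported cover interferon-induced genes, inflammatory mediators, immediate-early genes, MAPK output, extracellular matrix, mesenchymal, contractile and epithelial genes, invasion proteases, histones, E2F targets, mitosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid stress (ATF4 targets), endoplasmic reticulum chaperones, oestrogen receptor targets, messages with a terminal oligopyrimidine tract (TOP, mostly ribosomal proteins), endothelial and leukocyte markers, introduced genes and long non-coding RNAs. No long non-coding RNA was in the tables, so that list was not analysed here. The results of 1 further list and of some single genes are left out of the text. The groups, comparisons, lists, naming rule and 136 alternative settings were set before the data were examined. Alternatives used the size factors or the Wald test of DESeq2 1.42.0, no filter, all isoforms, a replicate term, other control arms, and leaving out each library in turn. Added after seeing the data were the dispersion of the ER-Src libraries for the BJ comparisons and the ER-Src second replicates alone.

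In main comparisons the named genes are the 8 largest increases and 8 largest decreases among called genes above the median abundance whose replicates did not overlap between groups, plus the 3 members with the smallest p in each list past camera. Secondary comparisons take 4 each way. Where nothing passed, the 5 smallest p are named, and pairs of single libraries take the 5 highest and 5 lowest ratios. Genes named outside this rule are said to be chosen after their values were seen. The models were tested on simulated data with 200 changed genes drawn around the measured spread. Variation between cultures beyond that spread was not simulated. At 1.5-fold, 2-fold and 4-fold, 40.3%, 65.7% and 96.6% of changed genes were called in BJ cycloheximide (1 of 9560 unchanged genes). ER-Src cycloheximide at 24 h gave 21.2%, 59.7% and 95.5% (10 of 9850), ER-Src RNA 15.2%, 54.5% and 92.4% (7 of 9610). Ribosome loading gave 14.1%, 23.9% and 69.2% in BJ (0 of 10595), 1.52%, 16.7% and 75.0% in ER-Src (2 of 10759). Tables and plots were made with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.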

Results

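The 36 libraries fell into 21 from MCF10A-ER-Src breast epithelial cells and 15 from the BJ fibroblast lines EH, EL and ELR. The ER-Src set held 7 RNA libraries, 10 footprint libraries made under cycloheximide and 4 made under harringtonine. Under cycloheximide, tamoxifen at 1, 4 and 24 h had 2 replicates each, and the 0 h and ethanol groups had 1 library each. The BJ set held 1 RNA library, 2 cycloheximide and 2 harringtonine libraries per line. No label says that replicates are separate cultures, so the p-values may measure technical spread. Between BJ replicates the counts varied barely beyond sampling noise (chi-square per gene 1.09 to 1.18, biological coefficient of variation 1.80% under cycloheximide). In the ER-Src cycloheximide libraries it was 3.85 to 5.27 per gene, with a coefficient of 13.9%. A log2 change is the first group named relative to the other, with its SE, and list medians are medians of log2 changes of the tested members. Counts of called list members are over all genes tested, and the count adjusted over the list alone is given where it differs. Genes said to have changed most, or among the largest changes, are so only among called genes above the median abundance whose replicates did not overlap between groups.

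Footprints carried the marks of the labels. Epithelial genes such as keratins and cadherins had a median of 258.6 CPM in the ER-Src cycloheximide libraries (n = 10) and 0.459 CPM in the BJ lines (n = 6), and extracellular matrix genes had 2.78 and 394.9 CPM. The median of leukocyte markers was at most 0.372 CPM in any library and that of endothelial markers at most 0.451 CPM. ESR1, whose ligand-binding part is in the fusion, ranged from 765.2 to 1691 CPM in ER-Src cycloheximide libraries and had no count in the BJ ones. The kinase gene SRC had 221.6 to 491.1 CPM and 21.2 to 30.4 CPM in those sets. HRAS, a small GTPase of growth signalling (GRCh37 chromosome 11, 532242 to 537321), gave 27.9 ± 2.43 CPM in EH, 33.7 ± 0.783 CPM in EL and 145.2 ± 8.70 CPM in ELR (SD, n = 2). TERT, the catalytic part of telomerase, had 353.8 ± 12.8, 173.1 ± 4.29 and 220.1 ± 25.6 CPM in EH, EL and ELR (SD, n = 2), and at most 0.360 CPM in ER-Src cycloheximide libraries. In RNA, SRC had 15.3 to 33.8 CPM in ER-Src and 10.8 to 15 CPM in BJ libraries. RNA of HRAS in EH, EL and ELR had 15.2, 18.5 and 32.2 CPM and that of TERT 115.7, 111.5 and 120.3 CPM (n = 1). In footprints, CDKN2A, which encodes the cell cycle inhibitor p16, had 20.9, 233.4 and 214.0 CPM in the 3 lines and no count in any ER-Src library. CDKN1A, which encodes the inhibitor p21, had 144.0, 44.5 and 24.4 CPM.

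The comparison of EL with EH asks what the step between these BJ lines changed in the messages being translated. In EL cells, interferon-induced genes had far more ribosome footprints and extracellular matrix genes far fewer than in EH. MX1, an antiviral GTPase (NM_001144925, chromosome 21, 42791947 to 42841998), rose from 11.7 ± 5.06 to 728.8 ± 38.6 CPM (SD, n = 2), a log2 change of 5.99 ± 0.13 (adjusted p = 3.99e-51). COL1A2, a chain of type I collagen (NM_000089, chromosome 7, 94024207 to 94060539), fell from 11870 ± 185 to 1203 ± 17.1 CPM, a log2 change of −3.30 ± 0.03 (adjusted p = 1.61e-76). Most genes on the lists of TOP messages, histones and E2F targets rose alongside, and most contractile, mesenchymal and protease genes fell.

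Of 24 interferon-induced genes 23 rose in EL and none fell, with a median of 4.09 (camera adjusted p = 2.50e-72, and adjusted p = 0.0275 with an estimated correlation). OAS1, a sensor of double-stranded RNA, rose by 6.79 ± 0.26 to 186.0 ± 1.10 CPM from 1.64 ± 0.227 CPM. OAS2 of the same family rose by 6.46, BST2, which tethers budding virus, by 5.96, and RSAD2, an antiviral enzyme, by 5.84. IFI27 rose by 5.81 ± 0.09 to 1210 ± 10.5 CPM, EPSTI1 by 5.40 and IFI6 by 5.06 to 2718 ± 112 CPM (SD, n = 2). HERC5, the ligase of the ubiquitin-like ISG15, had 400 counts in EL against 2 in EH, a ratio of 101.7 (95% interval 27.98 to 842.9).

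Of 25 matrix genes 24 fell and none rose, with a median of −2.02 (adjusted p = 9.21e-172, and adjusted p = 0.0129 with an estimated correlation). COL1A1 changed by −2.77 and FBLN1, a secreted matrix glycoprotein, by −4.54. Among the largest decreases were the hyaluronan-binding KIAA1199 (−6.48), the calcium-binding S100A4 (−5.83), the growth factor receptor PDGFRA (−5.75) and the proteoglycan decorin, DCN (−5.17, from 639.9 ± 17.6 to 17.6 ± 2.41 CPM). The complement protease MASP1 (−4.98), the elastic fibre protein FBLN5 (−4.93), MXRA5 (−4.78) and the prostaglandin synthase PTGS1 (−4.70) completed the set. In the list of invasion proteases 13 of 17 fell and 1 rose, with a median of −1.47 (adjusted p = 1.53e-59, and adjusted p = 0.0262 with an estimated correlation). Its examples were MMP3 (−4.21), the protease inhibitor TIMP1 (−2.16) and ADAMTS1 (−2.34). Mesenchymal genes fell in 11 of 14 and rose in 1 (median −1.05), with 12 falling adjusted over the list alone, and MMP2 (−3.77), which is also on the protease list, and fibronectin, FN1 (−1.26), were among them (adjusted p = 4.74e-16, and adjusted p = 0.0441 with an estimated correlation). Contractile genes fell in 13 of 17 and rose in 2, 3 adjusted over the list alone (median −0.78). FLNA (−1.53), TAGLN (−1.63) and CALD1 (−1.63), which bind or cross-link actin, led them (adjusted p = 1.32e-20, and adjusted p = 0.0441 with an estimated correlation).

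TOP messages, which encode ribosomal proteins and elongation factors, rose in 77 of 85 and fell in 1, with a median of 0.57 (adjusted p = 4.76e-38, and adjusted p = 0.0172 with an estimated correlation). RPS6 (0.88), RPL32 (0.84) and the nucleolar NPM1 (0.81) were the members with the smallest p. All 11 histone genes rose, with a median of 1.18 (adjusted p = 1.37e-25, and adjusted p = 0.0275 with an estimated correlation), among them HIST1H1E (1.81), HIST1H1C (1.41) and HIST1H3B (1.16). E2F targets, which serve DNA replication, rose in 19 of 28 and fell in 2, or 20 and 3 adjusted over the list alone (median 0.68). The helicase subunits MCM5 (1.16), MCM3 (1.25) and MCM4 (0.99) rose in this list (adjusted p = 4.03e-05, and adjusted p = 0.0441 with an estimated correlation). Mitosis genes went the other way, with 18 of 25 lower and 2 higher (median −0.36), including CENPF (−1.24), the kinase PLK1 (−0.86) and TOP2A (−0.85). That list passed at p = 3.02e-05 after adjustment but had an adjusted p = 0.0734 with an estimated correlation.

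Energy metabolism lists were called only at the preset correlation. Glycolysis rose in 14 of 20 and fell in 1 (median 0.43, adjusted p = 2.99e-06, but adjusted p = 0.131 with an estimated correlation), with GAPDH (0.45), LDHA (0.54) and TPI1 (0.60). Oxidative phosphorylation rose in 20 of 32 and fell in 2, 22 and 2 adjusted over the list alone (median 0.31), with ATP5A1 (0.41) and COX7A2 (0.44) up and NDUFA4 (−0.52) down (adjusted p = 0.00529, but adjusted p = 0.116 with an estimated correlation). Amino acid stress genes fell in 11 of 19 and rose in 1, 3 adjusted over the list alone (median −0.55). The serine enzyme PSAT1 (−1.35), the transporter chain SLC3A2 (−0.94) and the asparagine synthetase ASNS (−1.29) fell (adjusted p = 0.00248, but adjusted p = 0.116 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 14 of 20 and rose in 1 (median −0.29), with PDIA6 (−0.59), PDIA3 (−0.50) and HSP90B1 (−0.33) as examples (adjusted p = 0.0172, but adjusted p = 0.116 with an estimated correlation). Epithelial genes fell in 4 of 10 and rose in 1 (median −0.54), namely the junction proteins DSP (−2.35) and JUP (−2.78) and the integrin ITGA6 (−1.03) among others (adjusted p = 0.0397, but adjusted p = 0.150 with an estimated correlation).

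Other lists did not pass as sets. Cholesterol synthesis rose in 11 of 21 (12 adjusted over the list alone, median 0.28, adjusted p = 0.0781). MAPK output rose in 3 and fell in 9 of 19 (median −0.56, adjusted p = 0.0781). Inflammatory mediators rose in 1 and fell in 5 of 18, with a median of −0.04, or −0.23 with genes at 0 placed at their bound (adjusted p = 0.837). Immediate-early genes rose in 3 and fell in 4 of 17, 5 and 6 adjusted over the list alone (median −0.26, adjusted p = 0.837). Oestrogen receptor targets fell in 3 of 7, with a median of 0.02 against a downward set test (adjusted p = 0.0833).

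By edgeR, 4148 of 9999 genes differed between EL and EH, 1912 higher and 2236 lower, and 471 and 805 of these by at least 2-fold. With the larger spread of the ER-Src libraries in place of the BJ one, 2157 genes were called (862 higher and 1295 lower), and GAPDH, ATP5A1, COX7A2, HSP90B1 and PDIA3 were not among them. DESeq2 called 2457.

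**Figure D1:**
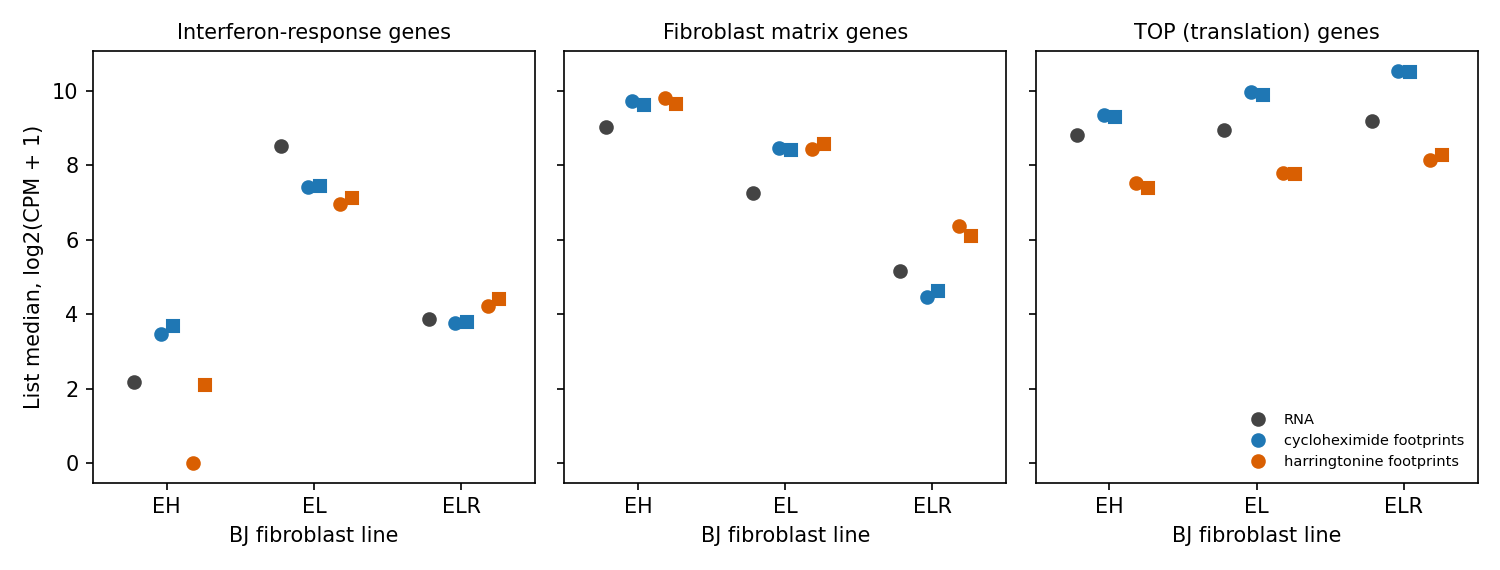
Median log2(CPM + 1) of the interferon, extracellular matrix and TOP lists (vertical axes) in each BJ library by line (horizontal axis); grey points are RNA, blue cycloheximide and orange harringtonine, circles replicate 1 and squares replicate 2. The EL medians of the interferon list (7.41 and 7.45 under cycloheximide, 8.53 in RNA) lie above those of EH and ELR.

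ELR differs from EL by the next step of the BJ series, and the question is what that step changed. ELR cells had far fewer footprints on interferon-induced genes than EL cells and fewer still on matrix genes, while most inflammatory mediators and TOP messages rose. IL1B, the cytokine interleukin 1 beta (NM_000576, chromosome 2, 113587328 to 113594393), rose from 3.48 ± 0.429 to 192.4 ± 17.9 CPM (SD, n = 2), a log2 change of 5.74 ± 0.19 (adjusted p = 1.54e-39). MX1 fell from 728.8 ± 38.6 to 3.33 ± 0.134 CPM, a log2 change of −7.74 ± 0.13 (adjusted p = 1.40e-57).

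Among abundant genes whose replicates did not overlap, the largest increases besides IL1B were G0S2, an inhibitor of fat breakdown (NM_015714, 5.94 ± 0.22, from 2.04 ± 0.321 to 129.8 ± 3.39 CPM), the secreted proteoglycan ESM1 (4.91), the crosslinking enzyme TGM2 (3.42) and ZNF185 (3.20). The chemokine IL8 rose by 3.15, the urokinase PLAU by 2.61 (72.4 ± 7.24 to 440.7 ± 17.9 CPM) and TMEM158, known to respond to Ras, by 2.56. Inflammatory mediators rose in 11 of 18 and fell in 2, with 12 rising adjusted over the list alone (median 1.26), CXCL1 (3.75) among them (adjusted p = 1.37e-06, and adjusted p = 0.0411 with an estimated correlation). Genes of MAPK output rose in 13 of 19 and fell in 1, 15 rising adjusted over the list alone (median 0.91). PHLDA1 (1.60), the phosphatase DUSP5 (2.02) and the cyclin CCND1 (0.77) were its examples (adjusted p = 7.99e-08, but adjusted p = 0.0730 with an estimated correlation). TOP messages rose in 84 of 85 (median 0.60), led by RPL13 (1.02), RPL37A (0.95) and RPL27 (0.87), with adjusted p = 2.68e-120 and adjusted p = 0.0411 with an estimated correlation. Histones rose in 9 of 11 and fell in 1 (median 0.30), with HIST1H2BD (0.71), HIST1H2BC (0.70) and HIST1H4C (0.54) (adjusted p = 1.33e-07, and adjusted p = 0.0411 with an estimated correlation).

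Of 24 interferon-induced genes 22 fell and none rose (median −3.56, adjusted p = 7.73e-74, and adjusted p = 0.0411 with an estimated correlation). BST2 (−7.77), MX2 (−7.04), IFI27 (−6.38) and IFI6 (−5.92) were among them, and RSAD2 had 2 counts against 467, a ratio of 215.5 (95% interval 59.34 to 1785). Matrix genes fell in 22 of 25 and rose in 1, 23 falling adjusted over the list alone, with a median of −2.78, or −2.47 with 5 genes at their bound (adjusted p = 1.46e-53, and adjusted p = 0.0411 with an estimated correlation). COL3A1 changed by −6.80, COL1A2 by −5.82 (to 21.6 ± 3.06 CPM) and COL1A1 by −2.58. The proteoglycan lumican, LUM, had 2 counts against 271, a ratio of 125.1 (95% interval 34.29 to 1038). DCN had no count in ELR against 86 in EL, at least 26.5-fold lower, and the desmosome protein DSP had none against 232, at least 71.4-fold lower. Mesenchymal genes fell in 10 of 14 and rose in 1, 11 falling adjusted over the list alone (median −1.34), among them CDH11 (−6.04), FN1 (−2.73) and N-cadherin, CDH2 (−1.03), with adjusted p = 5.41e-09 and adjusted p = 0.0411 with an estimated correlation.

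Contractile genes fell in 15 of 17 and none rose (median −0.91), with TAGLN (−3.35), tropomyosin TPM1 (−1.65) and the myosin light chain MYL9 (−1.55) (adjusted p = 2.80e-21, but adjusted p = 0.0539 with an estimated correlation). Amino acid stress genes fell in 11 of 19 and rose in 2 (median −0.62), among them the transcription factor ATF4 itself (−1.89), ASNS (−1.53) and PSAT1 (−0.79) (adjusted p = 0.000783, but adjusted p = 0.182 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 9 of 20 (median −0.15), with PDIA6 (−0.55), CALR (−0.48) and HSP90B1 (−0.40) (adjusted p = 0.00113, but adjusted p = 0.0730 with an estimated correlation). Mitosis genes fell in 13 of 25 and rose in 5, 14 falling adjusted over the list alone (median −0.16), including KIF20A (−0.86), NUSAP1 (−0.69) and TOP2A (−0.53) (adjusted p = 0.0182, but adjusted p = 0.239 with an estimated correlation). Lists that did not pass were cholesterol synthesis (0 up and 10 down of 21, adjusted p = 0.0899), immediate-early genes (5 and 2 of 17, adjusted p = 0.0852), oestrogen receptor targets (0 and 2 of 7, 3 down adjusted over the list alone, adjusted p = 0.111) and epithelial genes (6 and 3 of 10, adjusted p = 0.516). Oxidative phosphorylation (6 and 5 of 32) had an adjusted p = 0.604, and glycolysis (6 and 5 of 20, 7 and 5 adjusted over the list alone) had an adjusted p = 0.966. E2F targets (3 and 5 of 28, median 0.02, adjusted p = 0.678) and invasion proteases (6 and 8 of 17, median −0.24, adjusted p = 0.845) had set tests of the opposite sign to their medians.

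By edgeR, 3613 of 9999 genes differed between ELR and EL, 1733 higher and 1880 lower, and 271 and 700 of these by at least 2-fold. With the spread of the ER-Src libraries 1495 were called (566 higher and 929 lower), without CALR, HSP90B1 and TOP2A, and DESeq2 called 1820.

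Between the ends of the series, all 25 matrix genes were lower in ELR than in EH, with a median of −4.61 (adjusted p = 3.30e-199, but adjusted p = 0.0538 with an estimated correlation). All 85 TOP messages (median 1.17, adjusted p = 6.01e-113) and all 11 histones (median 1.44) were higher, each with an adjusted p = 0.0538 with an estimated correlation. IL1B (5.85), G0S2 (5.30), the tight junction protein CLDN11 (5.29, 448.0 ± 2.26 against 11.5 ± 2.74 CPM) and OASL (5.21), an interferon-induced gene, rose most. DCN was at least 953.5-fold lower, DSP at least 365.4-fold, PDGFRA at least 302.5-fold and MXRA5 at least 280.7-fold. Interferon-induced genes rose in 7 and fell in 8 of 24, 9 falling adjusted over the list alone (median 0.13, adjusted p = 0.446), while in RNA, with 1 library per line and no test, their median log2 ratio was 1.62, with 13 of 16 above 0 (random lists −0.42 to 0.42). E2F targets rose in 20 of 28 and fell in 2 (median 0.68, adjusted p = 0.00496), and mitosis genes fell in 21 of 25 and rose in 2 (median −0.52, adjusted p = 1.80e-05), each with an adjusted p = 0.151 with an estimated correlation. Contractile genes fell in 15 of 17 and rose in 1 (median −1.71, adjusted p = 0.0651 with an estimated correlation), mesenchymal genes fell in 13 of 14, 14 adjusted over the list alone (median −2.07, adjusted p = 0.0599 with an estimated correlation) and proteases fell in 12 of 17 and rose in 3 (median −1.36, adjusted p = 0.0694 with an estimated correlation). Amino acid stress genes fell in 12 of 19 and rose in 2 (median −1.33), inflammatory mediators rose in 9 of 18 and fell in 5, 10 rising adjusted over the list alone (median 1.11), and oxidative phosphorylation rose in 22 of 32 and fell in 1 (median 0.29), each with an adjusted p = 0.163 with an estimated correlation. Chaperones fell in 16 of 20 (median −0.72, adjusted p = 0.136 with an estimated correlation), and glycolysis rose in 14 of 20 and fell in 2 (median 0.38) and oestrogen receptor targets fell in 4 of 7 (median −0.77), each with an adjusted p = 0.197 with an estimated correlation. In all 5330 of 9999 genes differed, 2553 higher and 2777 lower.

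Harringtonine libraries give the same comparisons under the other drug and at a lower depth, again with counts taken as sums over whole coding regions. In EL against EH, MX1 had 157 counts against 1, a ratio of 105.0 (95% interval 18.58 to 4175), and OAS3 (4.59), IFI27 (4.59) and IFI6 (3.56) rose. KIAA1199 (−6.12), the sulfatase SULF1 (−5.30), MXRA5 (−4.38) and FBLN1 (−4.35) fell. Interferon-induced genes rose in 16 of 17, 17 adjusted over the list alone, with a median of 3.79, or 3.36 with genes at their bound (adjusted p = 7.16e-24, and adjusted p = 0.0262 with an estimated correlation). Matrix genes fell in 19 of 22 and rose in 1, 21 falling adjusted over the list alone (median −1.25, adjusted p = 8.27e-44, and adjusted p = 0.0321 with an estimated correlation). TOP messages rose in 8 of 84, 4 adjusted over the list alone (median 0.30, adjusted p = 0.00182, but adjusted p = 0.0650 with an estimated correlation). Histones rose in 7 of 10, 9 adjusted over the list alone (median 1.07), and proteases fell in 10 of 15 (median −1.04), each with an adjusted p = 0.0518 with an estimated correlation, and mesenchymal genes fell in 8 of 11 (median −1.01, adjusted p = 0.0650 with an estimated correlation). In ELR against EL, the guanine exchange factor DOCK4 (3.11), PLAU (2.65), PODXL (2.63) and the laminin chain LAMA5 (2.54) rose. COL3A1 had 2 counts against 418, a ratio of 261.7 (95% interval 72.00 to 2168), MX1 2 against 157, a ratio of 98.3 (26.76 to 818.9), CD248 was at least 17.95-fold lower and COL1A2 changed by −6.07. Interferon-induced genes fell in 15 of 17 (median −3.16, adjusted p = 3.87e-30, and adjusted p = 0.00916 with an estimated correlation). Matrix genes fell in 18 of 22, 19 adjusted over the list alone, with a median of −2.34, or −1.76 at the bounds (adjusted p = 8.38e-61, and adjusted p = 0.00573 with an estimated correlation), and TOP messages rose in 27 of 84, 28 adjusted over the list alone (median 0.43, adjusted p = 6.94e-09, and adjusted p = 0.0215 with an estimated correlation). In ELR against EH all 22 matrix genes fell (median −3.99, −3.95 at the bounds, adjusted p = 0.00484 with an estimated correlation) and 50 of 84 TOP messages rose, 54 adjusted over the list alone (median 0.75, adjusted p = 0.0395 with an estimated correlation). There, DOCK4 had 143 counts against 2 (ratio 38.2, 95% interval 10.38 to 318.5) and BNC1, an epithelial transcription factor, 85 against 3 (ratio 15.1, 5.008 to 74.86), PODXL rose by 4.09 and ARHGEF28 by 2.95. COL3A1 had a ratio of 616.7 (95% interval 170.0 to 5103) in favour of EH, COL1A2 changed by −8.97, MXRA5 was at least 123.5-fold lower and CD248 at least 44.3-fold.

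Of 3554 genes tested under harringtonine, 664 differed between EL and EH (271 higher and 393 lower), 582 between ELR and EL (228 and 354) and 1093 between ELR and EH (469 and 624). Of those also tested under cycloheximide, 632 of 663, 568 of 581 and 1063 of 1091 changed the same way there. The count for EL against EH was 415 without EL replicate 1, 429 without EH replicate 1 and 430 without EH replicate 2. That for ELR against EL was 346 without ELR replicate 2, 364 without EL replicate 1 and 369 without EL replicate 2.

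RNA from the BJ lines, with 1 library per line and hence no test, showed the interferon and matrix differences too. The interferon list had a median log2 ratio of 4.94 for EL to EH, all 24 members above 0 (random lists −0.30 to 0.14), and −3.66 for ELR to EL, with 0 of 24 above 0 (random lists −0.15 to 0.22). Matrix medians were −2.11 and −2.35, and the contractile list had −1.23 and −0.59. TOP messages had −0.02 for EL to EH, with 41 of 85 above 0 (random lists −0.26 to −0.05), and 0.31 for ELR to EL, with 74 of 85 above 0. The amino acid stress list had 0.43 for ELR to EL, with 15 of 18 above 0, where its footprints had a median of −0.62. MAPK output had 0.98 and inflammatory mediators 0.62 for ELR to EL, and E2F targets 0.56 for EL to EH. MX1 had 5903 counts in EL and 10 in EH (log2 ratio 8.94), and the secreted SCUBE3 had 5 and 691 (−6.57). Elastin, ELN, had 0 counts in EL and 348 in EH. In ELR against EL, ESM1 (4.81) and the Ras activator RASGRF2 (4.62) had the highest ratios that rest on more than 3 counts, and COL3A1 (−7.32), BST2 (−7.11), RSAD2 (−7.04), MX1 (−6.74) and IFI44L (−6.63) the lowest. At least 2-fold differences were counted for 494 genes higher and 701 lower of 8924 in EL to EH, and for 312 and 599 of 8866 in ELR to EL. Across genes, which are not independent replicates, Pearson's r between RNA and cycloheximide ratios was 0.81 for EL to EH (8529 genes) and 0.85 for ELR to EL (8494 genes).

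Ribosome loading asks which messages carried more or fewer footprints than their RNA accounts for. Each BJ line has 1 RNA library, so these p-values take the spread of RNA from the footprint replicates and cannot measure how RNA varies between cultures. TOP messages gained loading in EL over EH, with 64 of 85 higher and none lower, 74 and 1 adjusted over the list alone, and a median of 0.53 (adjusted p = 1.16e-60, and adjusted p = 0.00378 with an estimated correlation). HAS2, a hyaluronan synthase, gained 2.06 ± 0.25 (adjusted p = 4.29e-10), with 32.9 against 26.9 CPM in footprints and 67.5 against 227.9 CPM in RNA. HMGA2, a chromatin protein, gained 1.87 ± 0.35, with 22.5 against 12.7 CPM in footprints and 31.4 against 66.7 CPM in RNA. SCUBE3 gained 2.44 and HIST1H2AI 3.36, on 5 and 2 RNA counts in EL. Loading of MX1 changed by −3.19 ± 0.49 (adjusted p = 6.51e-07), with footprints of 756.0 against 12 CPM and 5903 RNA counts against 10. IFI27 (720 RNA counts against 1), BST2 (975 against 2) and CLDN11 (117 against 0) were lower too, without a size that such counts can give.

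Interferon-induced genes had lower loading in 10 of 24, 14 adjusted over the list alone (median −1.06, adjusted p = 1.10e-09, but adjusted p = 0.109 with an estimated correlation). Histones had higher loading in 5 of 11, 9 adjusted over the list alone (median 0.73, adjusted p = 0.0952 with an estimated correlation), contractile genes in 6 of 17 with 1 lower, 10 and 2 adjusted over the list alone (median 0.46, adjusted p = 0.186 with an estimated correlation), and mitosis genes lower in 6 of 25, 11 adjusted over the list alone (median −0.21, adjusted p = 0.118 with an estimated correlation). Matrix genes were higher in 2 and lower in 8 of 25, 3 and 9 adjusted over the list alone (median −0.19, adjusted p = 0.0140, but adjusted p = 0.346 with an estimated correlation). Glycolysis was higher in 5 of 20, 7 adjusted over the list alone (median 0.23, adjusted p = 0.189 with an estimated correlation). edgeR called 740 of 11083 genes, 423 higher and 317 lower, and with the size factors of DESeq2 755, of which 360 were higher and 395 lower. The DESeq2 test called 234 and the spread of the ER-Src libraries left 26.

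In ELR against EL, 12 of 21 messages of amino acid stress lost loading and 42 of 85 TOP messages gained it. ATF4, the transcription factor of that response, changed by −2.36 ± 0.19 (adjusted p = 4.69e-17), with footprints of 15 ± 0.644 against 56.2 ± 2.37 CPM (SD, n = 2) and RNA of 715.5 against 515.0 CPM. ALDH1L2, a mitochondrial folate enzyme, changed by −2.33, ASNS by −2.02 (footprints 39.1 against 112.2 CPM, RNA 57.6 against 40.7 CPM) and PSAT1 by −1.85 (103.9 against 178.7 CPM, RNA 189.9 against 90.8 CPM). Loading fell in 12 of 21 members of the list and rose in none (median −1.0, adjusted p = 3.01e-15, but adjusted p = 0.0859 with an estimated correlation). TOP messages rose in 42 of 85 and fell in 1, 58 and 2 adjusted over the list alone (median 0.28, adjusted p = 1.71e-39, and adjusted p = 0.0159 with an estimated correlation). Loading of TMEM126A (1.64), the prostaglandin synthase PTGS2 (1.64), the lysosomal CD68 (1.54) and DDX60L (1.43) rose. Footprints were higher in ELR for PTGS2 (26.8 against 5.29 CPM) and TMEM126A (73.65 against 56.13 CPM, on 22 against 45 RNA counts). Footprints of CD68 (128.3 against 145.2 CPM, on 20 against 57 RNA counts) and DDX60L (22.4 against 38.9 CPM, on 236 against 933) were lower, with a larger fall in the single RNA library. Glycolysis fell in 6 of 20, 7 adjusted over the list alone (median −0.20, adjusted p = 0.158 with an estimated correlation), contractile genes fell in 6 of 17 (adjusted p = 0.181 with an estimated correlation), and interferon-induced genes rose in 5 of 24 and fell in 1, 8 and 3 adjusted over the list alone (median 0.26, adjusted p = 0.181 with an estimated correlation). Calls numbered 332 of 11083, 114 higher and 218 lower, and with the size factors of DESeq2 292, of which 177 were higher and 115 lower. Without ELR cycloheximide replicate 1 there were 189 and without replicate 2 there were 206, DESeq2 called 105 and the spread of the ER-Src libraries left 6, ATF4, ALDH1L2, ASNS and PSAT1 among them.

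Whether the line differences depended on the drug was tested over 8818 genes. Between EL and EH 124 genes passed, 108 higher and 16 lower. They were tested against 0, while the median of all genes was 0.131. A positive value means a log2 change shifted upwards under harringtonine, which can be a larger rise or a smaller fall. For matrix genes it was a smaller fall, with medians of −1.25 under harringtonine and −2.02 under cycloheximide. Matrix genes were higher in 10 of 25, 11 adjusted over the list alone (median 0.44, adjusted p = 4.14e-36, and adjusted p = 0.00545 with an estimated correlation), and mitosis genes in 4 of 25, 5 adjusted over the list alone (median 0.23, adjusted p = 0.0126 with an estimated correlation). TOP messages were lower in 3 of 85, 7 adjusted over the list alone (median −0.22, adjusted p = 2.49e-05, and adjusted p = 0.00823 with an estimated correlation). The metallothionein MT1E (1.88, 29 harringtonine counts against 10) and GPR107 (20 against 3) were higher, as were ALDH16A1 and CNPY3 (each 14 against 0), and PPIP5K2 (−2.12), DDX20 (−1.85), MZT1 (−1.69) and SH3BP4 (−1.66) were lower. Between ELR and EL 8 genes passed, 3 higher (CCAR1 1.39, the actin-binding TMSB10 0.62, NME1-NME2 0.39) and 5 lower, with the histones HIST1H4L (−1.75), HIST1H2BC (−1.20) and HIST1H4H (−0.68) and the scaffold AHNAK (−0.40) among them. Histones were lower in 2 of 11 there (median −0.18, adjusted p = 0.0320 with an estimated correlation) and TOP messages had a median of −0.17 with 0 of 85 passing, 1 lower adjusted over the list alone (adjusted p = 2.34e-05, and adjusted p = 0.0118 with an estimated correlation). That count was 13 without ELR cycloheximide replicate 1 and 15 without EL cycloheximide replicate 2, and with the spread of the ER-Src libraries edgeR called 0 in either comparison (838 and 533 genes had an unadjusted p under 0.05 with the BJ spread).

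Induction of Src in the epithelial cells was followed over time against 4 uninduced libraries. At 1 h edgeR called only GADD45B, a stress-induced regulator (NM_015675, 1.87 ± 0.25, 55.9 ± 6.73 CPM with n = 2 against 14.7 ± 5.07 CPM with n = 4), and the kinase SGK1 (1.21 ± 0.17, 152.3 ± 24.6 against 66.6 ± 10.2 CPM), each with an adjusted p = 0.0133. Neither of these genes was called against the ethanol 1 h library alone. No list member passed over all 10195 genes, and adjusted over the list alone 2 inflammatory mediators were higher and 2 lower. Camera called TOP messages (median −0.14, adjusted p = 1.05e-07, but adjusted p = 0.779 with an estimated correlation) and inflammatory mediators (median 0.33, adjusted p = 0.0229) among 7 lists, none of which held with an estimated correlation (smallest adjusted p = 0.465 with an estimated correlation). Within replicate 1, 1 h against 0 h, the inflammatory median had the opposite sign, −0.08 with 7 of 18 above 0, and under harringtonine it was −0.78 with 5 of 15 above 0. Calls numbered 0 without tamoxifen 1 h replicate 1 or replicate 2 (798 at an unadjusted p under 0.05 with all libraries, 12 by DESeq2), 1 without ethanol 4 h and 6 without ethanol 24 h.

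At 4 h the claudin CLDN1 (2.42 ± 0.21, 126.2 ± 3.81 CPM with n = 2 against 24.5 ± 7.07 CPM with n = 4, adjusted p = 5.75e-05), the cytokine IL24 (3.06 ± 0.43, adjusted p = 0.00315), the protease inhibitor SERPINB3 (2.73) and SOCS3 (2.59), a feedback inhibitor of STAT3 signalling, increased most, and the transcription factor ZBTB38 (−0.67) fell. Inflammatory mediators rose in 6 of 20, 11 adjusted over the list alone (median 0.78, adjusted p = 2.24e-23, but adjusted p = 0.146 with an estimated correlation). Within replicate 1, 4 h against 0 h, their median was 0.27, with 11 of 19 above 0. Epithelial genes rose in 3 of 23, 7 adjusted over the list alone (median 0.24, adjusted p = 0.208 with an estimated correlation), interferon-induced genes in 3 of 18, 4 adjusted over the list alone (median 0.31, adjusted p = 0.345 with an estimated correlation), and immediate-early genes in 1 of 18, 5 adjusted over the list alone (median 0.31, adjusted p = 0.297 with an estimated correlation). There were 89 calls, 87 higher and 2 lower. Without tamoxifen 4 h replicate 1 there were 9, and IL24, SERPINB3, SOCS3 and ZBTB38 were no longer called, without the 0 h library there were 55 and without ethanol 1 h 54. Against ethanol 4 h alone there were 20, and with second replicates alone 3.

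By 24 h footprints had risen on 14 of 18 interferon-induced genes and 10 of 20 inflammatory mediators and had fallen on 74 of 85 TOP messages and 13 of 28 E2F targets. The set calls of these lists were lost when the correlation was estimated, from an adjusted p = 0.144 to an adjusted p = 0.257 with an estimated correlation. STC1, a secreted glycoprotein (NM_003155, chromosome 8, 23699442 to 23712319), rose from 18.4 ± 17.6 CPM (SD, n = 4) to 1506 ± 249 CPM (SD, n = 2), a log2 change of 6.38 ± 0.60 (adjusted p = 2.42e-06). The calcium-binding alarmins S100A8 (4.86, 192.5 ± 73.6 to 5583 ± 1065 CPM) and S100A9 (4.21, 629.2 ± 210 to 11620 ± 296 CPM) rose to high levels. SERPINB4 (6.37), SERPINB3 (6.06, 35.4 ± 31.5 to 2443 ± 355 CPM), IL24 (5.94), the lectin CLEC2B (5.16) and SOCS3 (4.98, 5.59 ± 2.64 to 166.8 ± 17.5 CPM) completed the largest increases among them. Among abundant genes whose replicates did not overlap, the largest decreases were the Wnt inhibitor DKK1 (−3.06, 166.2 ± 56.9 to 18.6 ± 9.83 CPM), the matrix protein TINAGL1 (−2.43), the retinal-oxidising enzyme ALDH1A3 (−2.38), AMIGO2 (−2.14), the guidance factor SEMA3C (−1.99), the growth factor CTGF (−1.97), the tubulin TUBA4A (−1.80) and the keratin KRT86 (−1.75).

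Interferon-induced genes rose in 14 of 18, 15 adjusted over the list alone (median 1.56), among them the RNA sensor DDX58 (2.28), the transcription factor IRF9 (2.69) and IFI6 (2.13) (adjusted p = 1.84e-13, but adjusted p = 0.144 with an estimated correlation). Inflammatory mediators rose in 10 of 20, and 11 rose and 1 fell adjusted over the list alone (median 0.93), with the chemokine CCL2 at 4.68 (adjusted p = 1.76e-08, but adjusted p = 0.249 with an estimated correlation). Within replicate 1, 24 h against 0 h, the inflammatory median was 0.16 (random lists −0.26 to 0.27), with 10 counts of IL8 against 105 (−3.48). Immediate-early genes rose in 10 of 18, and 11 rose and 1 fell adjusted over the list alone (median 0.87). FOS (2.93), the RNA decay factor ZFP36 (2.27) and the phosphatase DUSP1 (1.85) were their examples (adjusted p = 5.80e-10, but adjusted p = 0.144 with an estimated correlation). Invasion proteases rose in 9 of 16 and fell in 2 (median 1.23), with the cathepsins CTSB (3.16) and CTSL1 (3.05) and the inhibitor SERPINE2 (2.52) (adjusted p = 6.29e-10, but adjusted p = 0.161 with an estimated correlation). Cholesterol synthesis rose in 12 of 21, 14 adjusted over the list alone (median 0.60), with HSD17B7 (1.79) and HMGCS1 (0.84) (adjusted p = 8.41e-07, but adjusted p = 0.257 with an estimated correlation). The list was also higher at 24 h without induction, with a median log2 CPM of 7.02 in ethanol 24 h and 6.53 to 6.61 in the other uninduced libraries. Epithelial genes rose in 9 of 23 and fell in 1, 11 and 2 adjusted over the list alone (median 0.41), the keratins KRT6A (1.69) and KRT6B (3.33) and the desmosomal DSG3 (0.99) among them (adjusted p = 0.00144, but adjusted p = 0.323 with an estimated correlation). Glycolysis rose in 6 of 20 and fell in 1 (median 0.28), with the glucose transporter SLC2A3 (3.73), PDK1 (0.99) and PGK1 (0.68) (adjusted p = 0.00889, but adjusted p = 0.475 with an estimated correlation).

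TOP messages fell in 74 of 85, 81 adjusted over the list alone, and none rose (median −0.76, adjusted p = 1.44e-38, but adjusted p = 0.161 with an estimated correlation). RPS27 changed by −1.40, RPL13A by −1.06 and RPL37A by −1.04. E2F targets fell in 13 of 28, 20 adjusted over the list alone (median −0.64), including the replication clamp PCNA (−1.22) and the nucleotide enzymes RRM2 (−0.86) and TYMS (−0.75) (adjusted p = 3.36e-08, but adjusted p = 0.257 with an estimated correlation). Contractile genes fell in 3 of 14, 4 adjusted over the list alone (median −0.27), namely CTGF, the matrix-associated CYR61 (−1.74) and TPM1 (−1.04) (adjusted p = 0.00902, but adjusted p = 0.510 with an estimated correlation). Of 11 histones 1 fell, HIST1H4H (−0.98), with a list median of −0.49 (adjusted p = 0.0163, but adjusted p = 0.615 with an estimated correlation). Within replicate 1, 24 h against 0 h, the histone median had the opposite sign, 0.23, with 9 of 11 above 0. Lists that did not pass were mitosis (1 down of 25, adjusted p = 0.106), chaperones of the endoplasmic reticulum (0 of 20, adjusted p = 0.234), mesenchymal genes (1 up and 1 down of 10, 3 down adjusted over the list alone, adjusted p = 0.170), amino acid stress (4 and 4 of 18, 5 down adjusted over the list alone, adjusted p = 0.400), oxidative phosphorylation (0 of 32, adjusted p = 0.400) and oestrogen receptor targets (1 up of 6, adjusted p = 0.727). Matrix genes (2 up and 2 down of 14, adjusted p = 0.976) and MAPK output (2 and 1 of 19, median −0.06 with an upward set test, adjusted p = 0.833) did not pass either.

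At 24 h 1493 of 10195 genes were called, 897 higher and 596 lower, and 514 and 152 of these by at least 2-fold. Calls numbered 762 without tamoxifen 24 h replicate 1 and 704 without replicate 2, 796 against ethanol 24 h alone and 511 with second replicates alone. Among the genes named here, leaving out a 24 h replicate ended the calls of CTGF, TYMS and RRM2 (replicate 1) and of AMIGO2 and HIST1H4H (replicate 2).

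**Figure D2:**
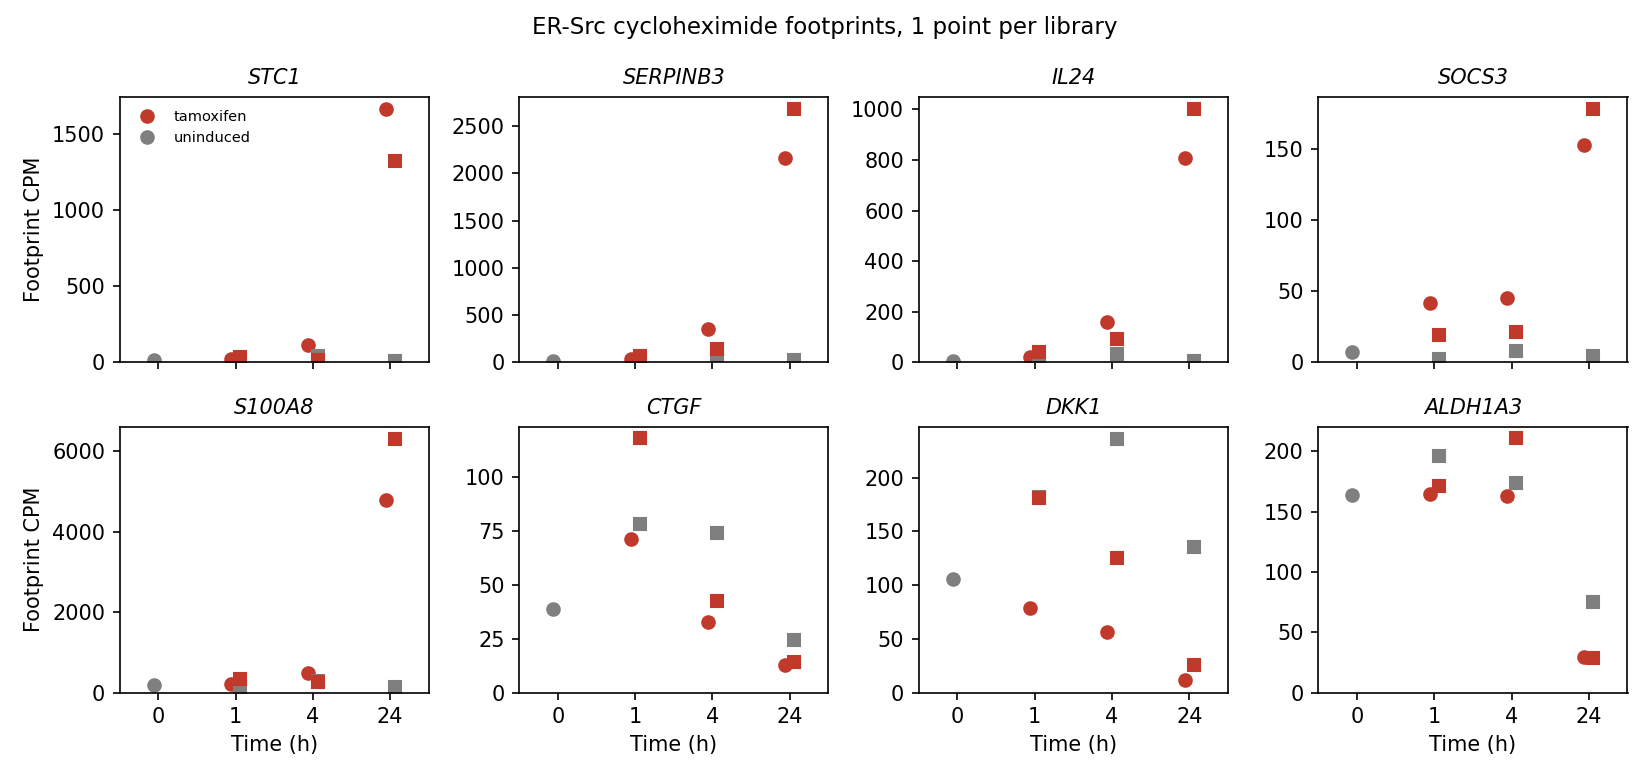
Footprint CPM (vertical axes, from 0) of 8 genes in each ER-Src cycloheximide library against hours (horizontal axes), with tamoxifen in red and uninduced libraries in grey, circles for replicate 1 and squares for replicate 2. STC1 stands at 1506 CPM on average at 24 h of tamoxifen against 18.4 CPM in the uninduced libraries.

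**Figure D3:**
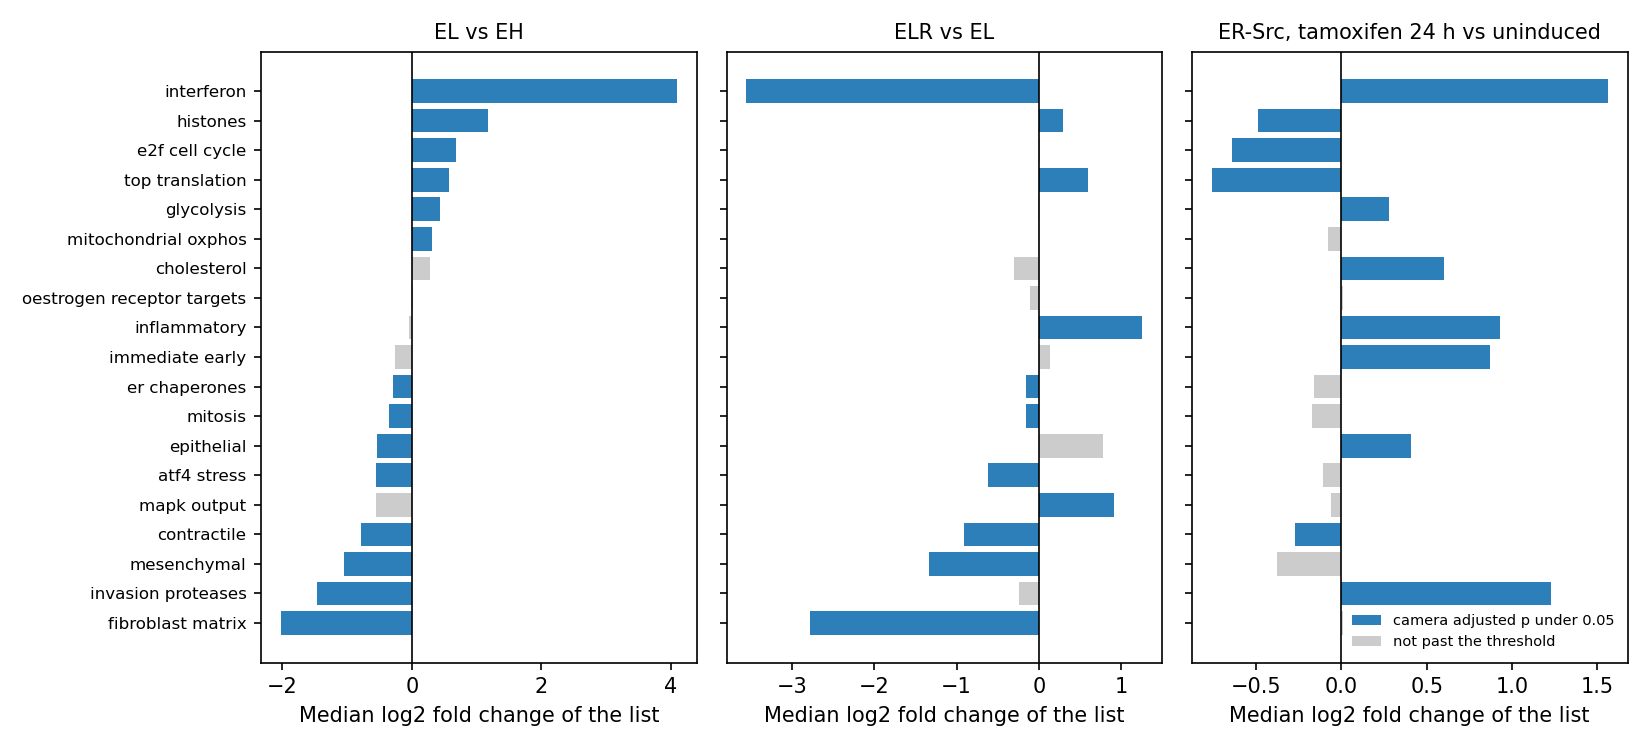
Median log2 change of the reported lists (horizontal axes, which differ in scale) for EL to EH, ELR to EL, and tamoxifen 24 h to uninduced cells under cycloheximide; blue bars passed camera at its preset correlation and grey bars did not. The bars do not show calls lost with an estimated correlation, which at 24 h of tamoxifen were all of them (smallest adjusted p = 0.144 with an estimated correlation). The interferon bars stand at 4.09, −3.56 and 1.56.

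Within the tamoxifen series, 24 h was set against 1 h, so that all libraries had the drug. STC1 (5.62), SERPINB4 (5.57), SERPINB3 (5.50), CLEC2B (5.00), IL24 (4.85), S100A8 (4.34), the transcription factor FOS (4.00) and SERPINB1 (3.85) rose most. TINAGL1 (−2.80), CTGF (−2.79), DKK1 (−2.72), ALDH1A3 (−2.54), CYR61 (−2.31), AMIGO2 (−2.30), SEMA3C (−2.06) and the stress gene GADD45A (−2.03) fell most. TOP messages fell in 56 of 85, and 68 fell and 1 rose adjusted over the list alone (median −0.58), with EEF1B2 at −1.57 (adjusted p = 4.46e-24, but adjusted p = 0.329 with an estimated correlation). Interferon-induced genes rose in 13 of 18, 14 adjusted over the list alone (median 1.39, IRF7 3.38), and immediate-early genes rose in 10 of 18 and fell in 1 (median 1.09), each with an adjusted p = 0.208 with an estimated correlation. Inflammatory mediators rose in 11 of 20, 12 adjusted over the list alone (median 1.14), and cholesterol synthesis in 12 of 21, 16 adjusted over the list alone (median 0.69, with the sterol enzyme MSMO1 at 1.48), and E2F targets fell in 8 of 28, 17 adjusted over the list alone (median −0.63, with GINS2 at −1.05), none of these below an adjusted p = 0.329 with an estimated correlation. There were 1390 calls, 792 higher and 598 lower, with 742 without tamoxifen 24 h replicate 1, 557 without its replicate 2 and 487 without tamoxifen 1 h replicate 2.

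RNA of the ER-Src cells was compared between 3 induced and 4 uninduced libraries that span 0 to 24 h. The smallest p belonged to the transcription factor ETS2 (2.16) and the signalling regulator RGS2 (2.63), each at an adjusted p = 0.298, followed by SOCS3 (4.24, adjusted p = 0.454), TARSL2 (1.00) and KLF5 (0.75), and none passed. edgeR called 0 of 9921 genes (592 at an unadjusted p under 0.05), and DESeq2 called 18. Without tamoxifen 1 h RNA there were 58 calls, and without tamoxifen 24 h RNA there were 2. Inflammatory mediators had a median of 0.73, 5 of 15 higher adjusted over the list alone (adjusted p = 1.31e-08, but adjusted p = 0.237 with an estimated correlation), interferon-induced genes 0.66, 5 of 14 higher adjusted over the list alone (adjusted p = 3.17e-08, but adjusted p = 0.269 with an estimated correlation) and E2F targets −0.19 (adjusted p = 3.63e-06, but adjusted p = 0.612 with an estimated correlation). TOP messages had 0.13 (adjusted p = 1.51e-05, but adjusted p = 0.708 with an estimated correlation).

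In the single RNA library at 24 h of tamoxifen against ethanol at 24 h, the highest ratios were those of STC1 (7.45), SERPINB4 (7.38), SERPINB3 (6.71), IL24 (6.67) and CLEC2B (6.06), with FGFR2 (−2.46), the histone chaperone ASF1B (−2.46) and ENC1 (−2.42) among the lowest that rest on more than 3 counts. Median log2 ratios were 1.99 for invasion proteases, 1.17 for inflammatory mediators (15 of 15 above 0), 1.02 for interferon-induced genes, 0.97 for immediate-early genes, 0.36 for cholesterol synthesis and −0.55 for E2F targets (2 of 25 above 0). TOP messages had 0.32 in RNA, 83 of 85 above 0 (random lists −0.03 to 0.11). At 4 h the inflammatory median was 0.89 (14 of 14 above 0) and SERPINB3 stood at 4.95. Across genes, Pearson's r between RNA and cycloheximide changes was 0.07, 0.40 and 0.75 at 1, 4 and 24 h.

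Ribosome loading at 24 h of tamoxifen fell for 41 of 85 TOP messages. RPS27 changed by −1.83 ± 0.24 (footprints 324.4 ± 28.4 CPM with n = 2 against 873.6 ± 163 CPM with n = 4, RNA 912.0 against 689.0 CPM). RPL13A changed by −1.68 (footprints 522.4 against 1112 CPM, RNA 1564 against 1039 CPM), the elongation factor EEF1A1 by −1.62 (footprints 632.5 against 1572 CPM, RNA 8326 against 6729 CPM) and TPT1 by −1.51. Of 85 TOP messages 41 fell and none rose, and 81 fell adjusted over the list alone (median −1.03, adjusted p = 3.57e-164, and adjusted p = 0.00385 with an estimated correlation). ASF1B was the gene with higher loading (2.61), on 6 RNA counts in the 24 h library. Histones had a median of 0.41 (adjusted p = 0.0124, but adjusted p = 0.937 with an estimated correlation), and no other list was called. edgeR called 49 of 11150 genes, 1 higher and 48 lower, with 11 without tamoxifen 24 h cycloheximide replicate 1 and 31 without ethanol 4 h RNA, and DESeq2 called 93.

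**Figure D4:**
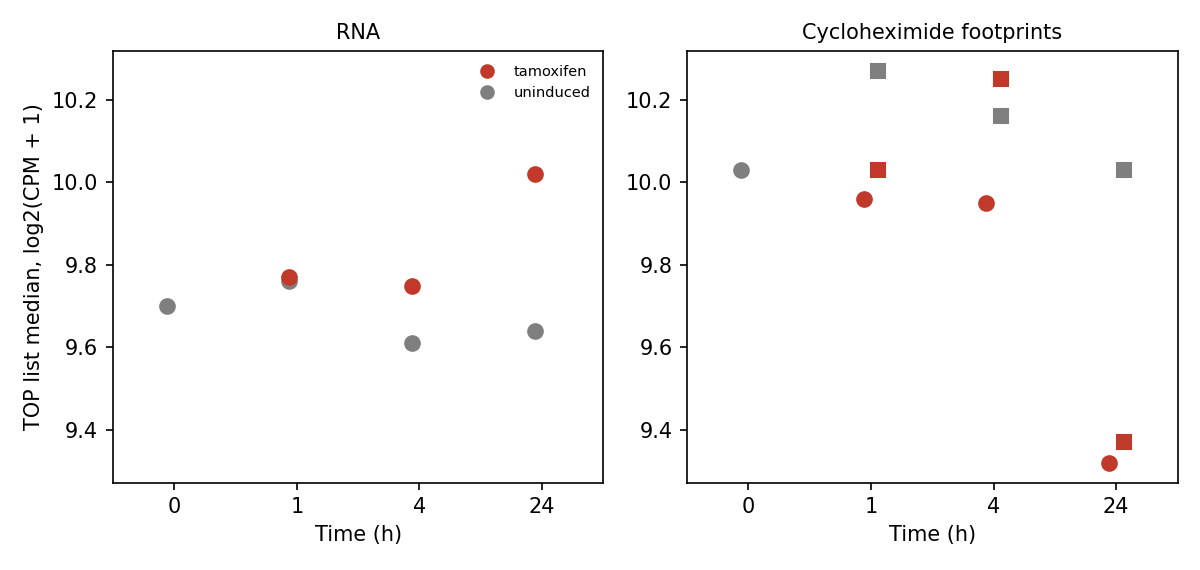
Median log2(CPM + 1) of the TOP list (vertical axes) in each ER-Src RNA and cycloheximide library against hours (horizontal axes), with tamoxifen in red and uninduced libraries in grey, circles for replicate 1 and squares for replicate 2. The list's median change at 24 h is −0.76 under cycloheximide and 0.32 in RNA against ethanol at 24 h.

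Single harringtonine libraries of the ER-Src cells were set against 0 h, beside cycloheximide replicate 1 at the same times. STC1 had 407 counts at 24 h and 1 at 0 h, SERPINB4 397 and 1, and SERPINB3 706 and 3. At 24 h the list medians under harringtonine and cycloheximide were 0.82 and 0.73 for cholesterol synthesis, −0.55 and −0.51 for E2F targets, −0.68 and −0.49 for mitosis, 1.18 and 0.80 for immediate-early genes, 0.97 and 0.16 for inflammatory mediators, 0.25 and 0.23 for histones, and 1.23 and 1.23 for invasion proteases. They differed in sign for TOP messages, at 0.22 (55 of 85 above 0) and −0.71 (1 of 85 above 0), for oxidative phosphorylation, at 0.56 and −0.14, for amino acid stress, at 0.13 and −0.32, and for oestrogen receptor targets, at −0.13 and 0.12. Across genes, Pearson's r between the drugs was 0.05, 0.22 and 0.45 at 1, 4 and 24 h.

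Harringtonine and cycloheximide footprints differed within each model for most genes. In the fibroblasts, SMG1 (3.60), DYNC1H1 (3.48), VPS13A (3.48) and MLL2 (3.46) were higher under harringtonine. Genes were tested against 0, while the median of all genes was −0.152. The histones HIST1H2AI (−3.43), HIST1H3A (−3.14) and HIST1H3D (−3.12) and the mitochondrial ribosomal MRPS6 (−3.11) were lower. TOP messages were lower in 81 of 85 and higher in 2 (median −1.85, adjusted p = 2.31e-29, but adjusted p = 0.554 with an estimated correlation), and oxidative phosphorylation was lower in 31 of 32 and higher in 1 (median −1.46, adjusted p = 1.57e-10, but adjusted p = 0.197 with an estimated correlation). In the ER-Src cells ATAD2 (2.59), RRBP1 (2.56), TOP2A (2.51) and SMARCA4 (2.43) were higher, and PI3 (−4.09), DYNLT1 (−3.93), PFDN4 (−3.92) and TMEM258 (−3.90) were lower. TOP messages were lower in 79 of 85 and higher in 3 (median −1.81, adjusted p = 6.16e-36, but adjusted p = 0.420 with an estimated correlation), and all 11 histones (median −1.80) and 29 of 32 oxidative phosphorylation genes (median −1.71) were lower, each with an adjusted p = 0.367 with an estimated correlation. edgeR called 5378 of 8365 genes in the fibroblasts (2504 higher and 2874 lower) and 5004 of 8996 in the ER-Src cells (2420 and 2584). Coding length was not a term of these models, so differences by gene class and by coding length cannot be told apart here.

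The models were set side by side through ELR against EL and tamoxifen at 24 h. Across 9176 genes their footprint changes had a Pearson's r of −0.09 (95% interval −0.11 to −0.07, genes not being independent replicates) and Spearman's rho −0.10. Genes higher in both numbered 136, where 124.8 were expected by chance (Fisher's exact test, p = 0.258), and genes lower in both 101 against 91.2 (p = 0.260). Opposite changes were called for 433 genes, where 214.3 were expected by chance. In a test chosen after the result was seen, 225 genes were higher in ELR and lower with tamoxifen against 97.0 expected (Fisher's exact test, p = 1.97e-40), and 208 were lower in ELR and higher with tamoxifen against 117.3 (p = 6.99e-19), genes again not being independent. Chosen after their values were seen, TGM2 (3.42 and 4.14), STC1 (2.16 and 6.38), the collagenase MMP1 (1.94 and 4.44) and the lipid transporter ABCA1 (2.31 and 5.53) rose in both, and PTGS1 (−4.28 and −2.61) and thrombospondin, THBS1 (−1.43 and −1.45), fell in both. MX1 (−7.74 and 4.61), IRF9 (−3.70 and 2.69), CCL2 (−6.72 and 4.68) and the complement protease C1R (−3.01 and 2.93) changed in opposite directions.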

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

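For the interferon list, the look at RNA and the count of EL libraries, for the TOP list the test in cycloheximide libraries alone, and for the amino acid stress list both tests were chosen only after the result was seen.

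Interferon-induced genes were higher in EL than in EH and ELR, with medians of 4.09 against EH and −3.56 for ELR against EL. A preparation effect in the footprint libraries alone would leave RNA alike, but the RNA median was 4.94 for EL to EH. A single mislabelled or mixed EL library would leave the others in place, but 5 of 5 EL libraries (RNA, cycloheximide and harringtonine) had a median above each EH and ELR library of its kind. The step between lines, which the design names, stays open, as does the state of the one EL culture or batch that all its libraries may share. No label names separate clones or cultures of EL, so a hypothesis that the introduced genes raise this response in EL was not tested.

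Ribosome loading of TOP messages was lower at 24 h of tamoxifen, with a median of −1.03. Short coding regions might give such a fall, but 255 matched non-members (3 per member, median coding length 612 against 495 bases, average log2 CPM 8.81 against 9.99) had a median of −0.18, with quartiles of −0.31 and −0.01 against −1.19 and −0.75 for the list. Reads shared with processed pseudogenes would spare members that have few, but the 33 members with at most 6 named pseudogenes had a median of −0.93 (SE 0.06) and the highest group −1.06. Cycloheximide alone gave −0.76, with 85 of 85 members below the uninduced mean in both 24 h libraries. RNA gave 0.32 against ethanol at 24 h. As loading subtracts RNA, the single 24 h RNA library stays open as the cause. A candidate explanation is lower translation of these messages, but the single harringtonine library at 24 h gave 0.22 for the list where cycloheximide replicate 1 gave −0.71, and that difference between the drugs was not tested.

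Ribosome loading of amino acid stress genes was lower in ELR than in EL, with a median of −1.0 (camera adjusted p = 3.01e-15, but adjusted p = 0.0859 with an estimated correlation). Cycloheximide alone gave −0.62 (SE 0.20, 19 members) and RNA 0.43, the opposite sign. As loading subtracts RNA, this cannot exclude the single RNA library of each line as the cause. RNA and footprints from cultures in different nutrient states cannot be told apart from a change in translation either, with 1 RNA library per line. A change in the translation of ATF4 and its targets between the lines stays open as a hypothesis.

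In the tests of differences between changes, 1390 genes differed between 24 h and 1 h of tamoxifen. Between EL and EH 740 genes differed in ribosome loading. Between ELR and EL 332 did. At 24 h of tamoxifen 49 genes differed in loading. The effect of line depended on the drug for 124 genes in EL against EH and for 8 in ELR against EL.

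Among 4 uninduced RNA libraries, ethanol 24 h had a contractile list median of 4.94 (log2 of CPM + 1) where the others had 6.07 to 6.28. Its mesenchymal median was 2.32, where the others had 2.56 to 2.59. Ethanol 1 h RNA had a total count of 2881484, where the others had 2465610 to 2480435. Among 4 uninduced cycloheximide libraries, the cholesterol list median was 7.02 in ethanol 24 h and 6.53 to 6.61 in the others. The leukocyte median was 0.40 in the 0 h library and 0.00 in the others. These 5 values stood out by a test for a single distant value applied to 46 measures, which by chance marks about 1 in 20.

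Other splits of the same libraries were counted for comparisons with at least 3 libraries a side. For ER-Src RNA the real split called 0 genes, so all 35 splits reach as many by construction and the count decides nothing (highest other 10; edgeR, 592 genes at an unadjusted p under 0.05, DESeq2 18). For harringtonine against cycloheximide in the fibroblasts the real split called 5378 genes and was the 1 split of 100 drawn to reach that, with 1085 in the highest other. In the ER-Src cells the real split called 5004 by edgeR, the 1 split to do so of the 32 that could be fitted, with 0 in the highest other. In the other 3 the sides could not be told from time. The real split thus ranked first in each model, but this does not exclude chance. Every other split puts both drugs on each side, which widens the spread and lowers its calls, and libraries that may share a culture are not independent units.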

How the results depend on the processing

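The BJ counts under the spread of the ER-Src libraries and the counts from second replicates alone were chosen only after the result was seen. No named gene reversed direction under the alternatives run, and no list did with the size factors of DESeq2 or a replicate term. Direction was not compared with an estimated correlation or fry, the other alternatives run on lists. For named genes, 316 of 316 values kept their side of the threshold with those size factors, and 1531 of 1652 leaving out 1 library. Of 145 list calls by camera, 30 held with an estimated correlation, 113 with fry, 141 with those size factors and 124 of 131 with a replicate term. Counts of calls stayed within 1.5 times in 18 of 18 comparisons with those size factors, 8 of 18 with the DESeq2 Wald test, 14 of 18 with no filter, 3 of 16 with all isoforms, 15 of 16 with a replicate term and 81 of 107 fits that left out 1 library. A joint fit of both drugs kept 3 of 3. Depth limits the harringtonine results: totals of 129175 to 214806 in the BJ lines left 3554 genes to test against 9999 under cycloheximide. Leaving out a single RNA library could not be fitted in 5 cases. Residuals of like-numbered replicates correlated across genes at −0.03, 0.15 and 0.22 in ER-Src and at 0.00 to 0.05 in BJ libraries. Since the correlation was not above 0.1 for every pair, the numbers were not taken to pair the samples, though 2 of the 3 ER-Src values leave some shared structure open.

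With the DESeq2 Wald test, cycloheximide calls were 2457 (EL against EH) and 1820 (ELR against EL), and harringtonine calls 254, 188 and 497 (ELR against EH). They were 12 at 1 h of tamoxifen, 18 in ER-Src RNA, 234 and 105 for BJ loading and 93 for ER-Src loading, and the cause was not tested. All isoforms, which test more transcripts, gave 7751, 6932 and 10072 under cycloheximide, 1243, 1009 and 2044 under harringtonine, 5, 150 and 2999 at 1, 4 and 24 h, 2698 for 24 h against 1 h, 1386 and 659 for BJ loading and 191 for the drug term of EL against EH. With no filter there were 22 calls at 1 h, 174 at 4 h, 3 in ER-Src RNA and 13 for the drug term of ELR against EL, and a replicate term gave 4 at 1 h; the cause was not tested. The spread of the ER-Src libraries, larger by construction, gave 2157 and 1495 under cycloheximide, 367 under harringtonine (ELR against EL), 26 and 6 for BJ loading and 0 and 0 for the drug terms by edgeR. With fewer control libraries, the time-matched ethanol library gave 1, 20 and 796 calls at 1, 4 and 24 h, and ethanol alone gave 55 at 4 h. Second replicates alone, which also leave out tamoxifen replicate 1, gave 0, 3 and 511. In RNA, ethanol alone with time as a block gave 3.

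Leaving out 1 library gave 3054 to 3730, 2556 to 3103 and 4326 to 4889 calls for the BJ lines under cycloheximide (EL against EH, ELR against EL, ELR against EH) and 415 to 466, 346 to 399 and 756 to 873 under harringtonine. For tamoxifen the ranges were 0 to 6 at 1 h (0 without either 1 h replicate), 9 to 82 at 4 h (9 without replicate 1), 704 to 1963 at 24 h (704 without replicate 2) and 487 to 947 for 24 h against 1 h (487 without 1 h replicate 2). ER-Src RNA gave 0 to 58 (58 without the 1 h library). Loading gave 581 to 720, 189 to 311 and 11 to 63, the drug terms 91 to 124 and 6 to 15, and harringtonine against cycloheximide 4269 to 5574 and 4221 to 4776.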

Other observations

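No test in this part was chosen after the result was seen. Between 24 h and 1 h of tamoxifen, invasion proteases rose in 6 of 16 and fell in 1, 9 and 2 adjusted over the list alone (median 0.85). Epithelial genes rose in 9 of 23 and fell in 1, 11 and 2 adjusted over the list alone (median 0.48), and glycolysis rose in 5 of 20, 7 adjusted over the list alone with 1 lower (median 0.27). Contractile genes fell in 3 of 14, 6 adjusted over the list alone (median −0.26). Each of these lists passed camera at its preset correlation and had an adjusted p = 0.329 with an estimated correlation. Histones fell in 2 of 11, 5 adjusted over the list alone (median −0.70, adjusted p = 0.407 with an estimated correlation).

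Under harringtonine, ELR had fewer footprints than EH on 10 of 12 contractile genes (median −1.56) and on 9 of 11 mesenchymal genes (median −2.11), each with an adjusted p = 0.0772 with an estimated correlation. Histones were higher in 9 of 10 there (median 1.17, adjusted p = 0.104 with an estimated correlation), and proteases were lower in 10 of 15 and higher in 2 (median −0.81, adjusted p = 0.117 with an estimated correlation). Between ELR and EL, contractile genes fell in 8 of 12, 9 adjusted over the list alone (median −0.71), and mesenchymal genes in 4 of 11, 5 adjusted over the list alone (median −0.79, −0.74 with genes at their bound), each with an adjusted p = 0.103 with an estimated correlation. MAPK output rose in 3 of 5 and fell in 1 (median 0.57, adjusted p = 0.182 with an estimated correlation).

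In ribosome loading of ELR against EL, E2F targets fell in 2 of 28, 9 adjusted over the list alone (median −0.19, adjusted p = 0.158 with an estimated correlation). Immediate-early genes rose in 1 of 17 (median 0.38, adjusted p = 0.181 with an estimated correlation). In EL against EH, mesenchymal genes rose in 3 of 14 (median 0.45, adjusted p = 0.156 with an estimated correlation) and amino acid stress genes fell in 2 of 21, with 4 falling and 1 rising adjusted over the list alone (median −0.33, adjusted p = 0.189 with an estimated correlation).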
